A study of Piriqueta cistoides subsp. caroliniana with 18 samples.

How the data were processed

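Leaf RNA of 18 plants was measured on 18 two-colour arrays, 3 plants in each of 6 groups (the morphotypes caroliniana, viridis and hybrid, each well-watered or after drought). Per the labels, cuttings were grown in sand in a greenhouse at 35/27 °C with a day length of 12 h, and drought came in 4 cycles over 36 days. The authors amplified 4 µg of total RNA per sample, reverse transcribed 3.5 µg of the amplified RNA and labelled it with Cy3 and Cy5. The deposited values are log ratios of both channels, recorded as log2 because that base is usual for such arrays, but neither the base nor the channel order is stated. Values of -5.83 to 5.58 exclude base 10, since a 16-bit scanner spans 4.82 log10 units, but base 2 and base e cannot be separated, so effects are given in log-ratio units. The means of the arrays lay between -0.00144 and 0.0112 and the medians between -0.0451 and 0.0668, as left by the authors' normalisation, whose method is not stated.

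The direction of the ratio is not settled either, because the order of the plant codes in the titles and the order of the worded treatments contradict each other. Cy5 over Cy3 was used throughout, and signs are stated on that reading. Turning the sign of any of the 6 arrays that pair drought with well-watered plants raised the residual sum of squares (ratios 1.06 to 1.29), so these arrays share 1 direction, but this does not say which. Turning the array of viridis well-watered plant 3 and hybrid well-watered plant 2 lowered it (0.951). The channel intensities and backgrounds were not analysed here, so signal over background is unknown.

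Of 9600 probes, 1424 had no value on any array, the others had values on at least 12, and 5371 on all 18. Probes with values on at least 14 arrays were tested (7880). Missing values were not filled in, and the arrays were neither centred nor scaled again. Gene symbols came from the table of soybean genes supplied for the probes: 552 probes had an entry, 546 of them 1 symbol and 6 several, which were left unnamed, and 9048 had none. Of those with 1 symbol, 179 carried a LOC number only.

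The arrays form 1 closed loop in which neighbouring arrays share a plant. Each probe was fitted by generalised least squares with 6 group means, a dye intercept and the plant as a random effect that enters with opposite signs on its Cy5 and Cy3 array. The variance of plants relative to arrays was set to 1 value over all probes by restricted maximum likelihood (0.25, a gain of 650.6 in log likelihood over 0). Tests used limma 3.58.1 with MASS 7.3.60.0.1 in R 4.3.3: moderated tests from empirical Bayes (prior df 3.95, residual df 12), two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. A called probe is one past that threshold. Comparisons were the drought effect averaged over and within morphotypes, its interaction with morphotype (F test with 2 numerator df), caroliniana against viridis, and the hybrid against each parent, against both and against the mid-parent value, over both treatments and within each. Similarity of drought effects was described by correlation across probes. Plant values were estimated from the loop and centred on 0 over plants, for complete probes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

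Comparisons, tests, thresholds, the rule for named genes, 16 gene lists and the alternatives were fixed before the data were examined, except where stated. The rule named, among called probes with 1 symbol that kept their sign with each plant left out, the 10 with the largest change in each direction for the averaged drought effect and for caroliniana against viridis and the 5 largest for other comparisons. Where none was called it took the 5 named probes with the smallest p, and in addition up to 4 members per list. At most 2 probes without a name per direction were added. No fixed list reached the minimum of 3 matched members (2 for antioxidant enzymes, 1 for phenylpropanoid and flavonoid genes, 1 for reference genes), so the planned camera and fry tests of them were not run. A further 9 lists from soybean symbols were formed later and tested with camera on gene means (on each array, of the gene's probes with a value there), with a preset correlation of 0.01 and with an estimated one.

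The fit was tested on simulated data with the same loop. Of 50 probes per size given an averaged drought effect of 0.25, 0.5, 1 or 2, it called 52, 92, 100 and 100%, with 11 false calls among 183, and of those given an effect in caroliniana alone it called 18, 66, 98 and 100%. The simulated errors were normal, followed the fitted model and were independent between probes. In the real data the first component held 39.7% of the residual variance, so these rates need not hold there. Alternatives were arrays treated as independent, the array the submitters marked BAD left out, arrays centred on medians, arrays scaled to 1 median absolute deviation, complete probes only, a replicate block for plant number, no dye term, array weights, each plant left out, and a threshold of 0.10. The array marked BAD is that of viridis drought plant 3 and hybrid drought plant 2. Added after the data were seen were the set tests without hybrid well-watered plant 2 and with gene means of complete probes where a gene has any, the array with most missing values left out (2214 of the probes with values), the first principal component of the residuals as a covariate, and both plants in doubt left out (hybrid well-watered plant 2 and viridis drought plant 3). Other splits of the plants into groups of the same sizes were counted, 10 within a morphotype and 100 drawn for the other comparisons.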

Results

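Leaf RNA of Piriqueta cistoides subsp. caroliniana (Piriqueta caroliniana in the series title), a perennial herb with the morphotypes caroliniana and viridis and their hybrid, was compared between well-watered plants and plants taken through 4 cycles of drought over 36 days. The 18 plants, grown from cuttings, formed 6 groups (3 morphotypes by 2 treatments) of 3 plants each. They were hybridised in pairs on 18 arrays that close into 1 loop, so that each plant lay on 2 arrays, once in each dye. The arrays carried soybean cDNA clones, so each value comes from hybridisation across species and bears the soybean gene name of its clone where there is one. Of 9600 probes, 8176 had values and 7880 had values on at least 14 arrays and were tested; 467 of these, for 309 genes, had a single gene symbol. The number of arrays limits the precision.

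Drought was set against the well-watered state first over all morphotypes, as the mean of the 3 drought effects. The largest changes with a gene name were in CAB3, a chlorophyll a/b-binding protein of the light-harvesting complex. All 4 of its probes changed to the positive side, by 3.56 ± 0.519 (SE) for Gm01099, 2.38 ± 0.446 for Gm05769, 1.88 ± 0.167 for Gm06115 and 1.79 ± 0.164 for Gm05985. These values are drought minus well-watered in log-ratio units, on the reading that the deposited ratio is Cy5 over Cy3. The files leave that reading open, and the opposite reading would exchange the positive and the negative side of every comparison. The base of the logarithm is open as well, so that the effect of Gm06115 is a 3.68-fold difference if the base is 2 and 6.55-fold if it is e. CHLH, the subunit H of magnesium chelatase in chlorophyll synthesis, changed on the side of CAB3 by 0.77 ± 0.0992 for Gm06139, while its other probe Gm06047 had 0.72 ± 0.181 (adjusted p = 0.0539).

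CYP98A2, a cytochrome P450 of the phenylpropanoid pathway, changed on the same side with 1 of its 3 probes, by 0.93 ± 0.143 for Gm08062. The other probes had 0.04 and -0.07 and did not pass the test. MIPS, the myo-inositol-3-phosphate synthase that makes the precursor of inositol compounds, changed by 0.31 ± 0.0712 for Gm03671 and 0.28 ± 0.0536 for Gm05530, and a further probe, Gm00068, had 0.43 ± 0.129 (adjusted p = 0.123). LOC547820 changed by 0.47 ± 0.106 with 1 of its 5 probes. On the opposite side lay LOC548038 with 1 of its 6 probes at -0.42 ± 0.0743, MET2 with 1 of 4 at -0.31 ± 0.0661, LOC547870 at -0.30 ± 0.0739 and DR1 with 1 of 2 at -0.27 ± 0.0611. Of the 6 arrays that paired a drought with a well-watered plant of the same morphotype, 6 of 6 showed the direction of the called probe of CAB3 Gm06115, CAB3 Gm05985, CHLH, CYP98A2, LOC547820, LOC548038, LOC547870 and DR1. It was shown by 5 of 6 for the called probes of MIPS and MET2. CAB3 Gm01099 had values on 3 of these arrays and Gm05769 on 4, and all of them showed the direction.

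By the limma test with the plant as a random effect, 153 probes passed an adjusted p of 0.05 for the averaged drought effect, 118 on the positive side (77.1%) and 35 on the negative side. The adjusted p of the CAB3 probes was 0.0013 for Gm01099, 0.00849 for Gm05769, 3.29e-06 for Gm06115 and 3.77e-06 for Gm05985. It was 1.24e-04 for CHLH, 8.42e-04 for CYP98A2, 0.0286 and 0.00812 for MIPS, 0.0266 for LOC547820, 0.00875 for LOC548038, 0.0184 for MET2, 0.0460 for LOC547870 and 0.0251 for DR1. Only 9 of the positive and 4 of the negative calls had a gene name. The probes without one included the largest changes, 4.2 ± 0.573 for Gm05767 and 3.94 ± 0.425 for Gm13870 on the positive side and -1.67 ± 0.195 for Gm03935 and -1.09 ± 0.160 for Gm04675 on the negative side. All 153 kept their sign when each plant was left out in turn, and all had the same sign in the 3 morphotypes. The choice of probes by the averaged effect favours both results, so they are not separate evidence. The count was 373 without hybrid well-watered plant 2, whose median position on the probes called in the hybrid without it was 0.888 on a scale from 0 at the other well-watered to 1 at the drought plants, and 100 without viridis well-watered plant 2. CAB3 Gm01099 ran from 2.37 without viridis drought plant 1 to 4.3 without caroliniana drought plant 1, and missed the threshold without viridis well-watered plant 2 (2.64, adjusted p = 0.0532). Gm05769 missed it without viridis well-watered plant 1 (1.79), viridis well-watered plant 2 (2.23), viridis drought plant 1 (2.21) or viridis drought plant 2 (1.75).

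The calls of several of the smaller named changes ended without 1 or another of many plants, while their effects kept their sign. Of the 18 plants left out in turn, 13 ended the call for LOC547870, 12 for DR1, 10 and 3 for the MIPS probes, 8 each for LOC547820 and MET2 and 4 for LOC548038, with effects of -0.36 to -0.26 for LOC547870, -0.30 to -0.22 for DR1, 0.27 to 0.35 and 0.24 to 0.31 for MIPS, 0.40 to 0.52 for LOC547820, -0.38 to -0.24 for MET2 and -0.46 to -0.34 for LOC548038. The calls of CAB3 Gm06115, CAB3 Gm05985, CHLH Gm06139 and CYP98A2 Gm08062 passed without each of the 18. The share of positive calls was 77.1% with the deposited scaling, 61.3% when arrays were weighted by quality and treated as independent, 64.2% with the first component of the residuals as a covariate, and 66.5% without both hybrid well-watered plant 2 and viridis drought plant 3. The count was 252 when the arrays were scaled alike, 302 with weighted, independent arrays, 299 with that covariate and 304 without both plants, and the 153 were all among the 252 and the 299.

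**Figure D1:**
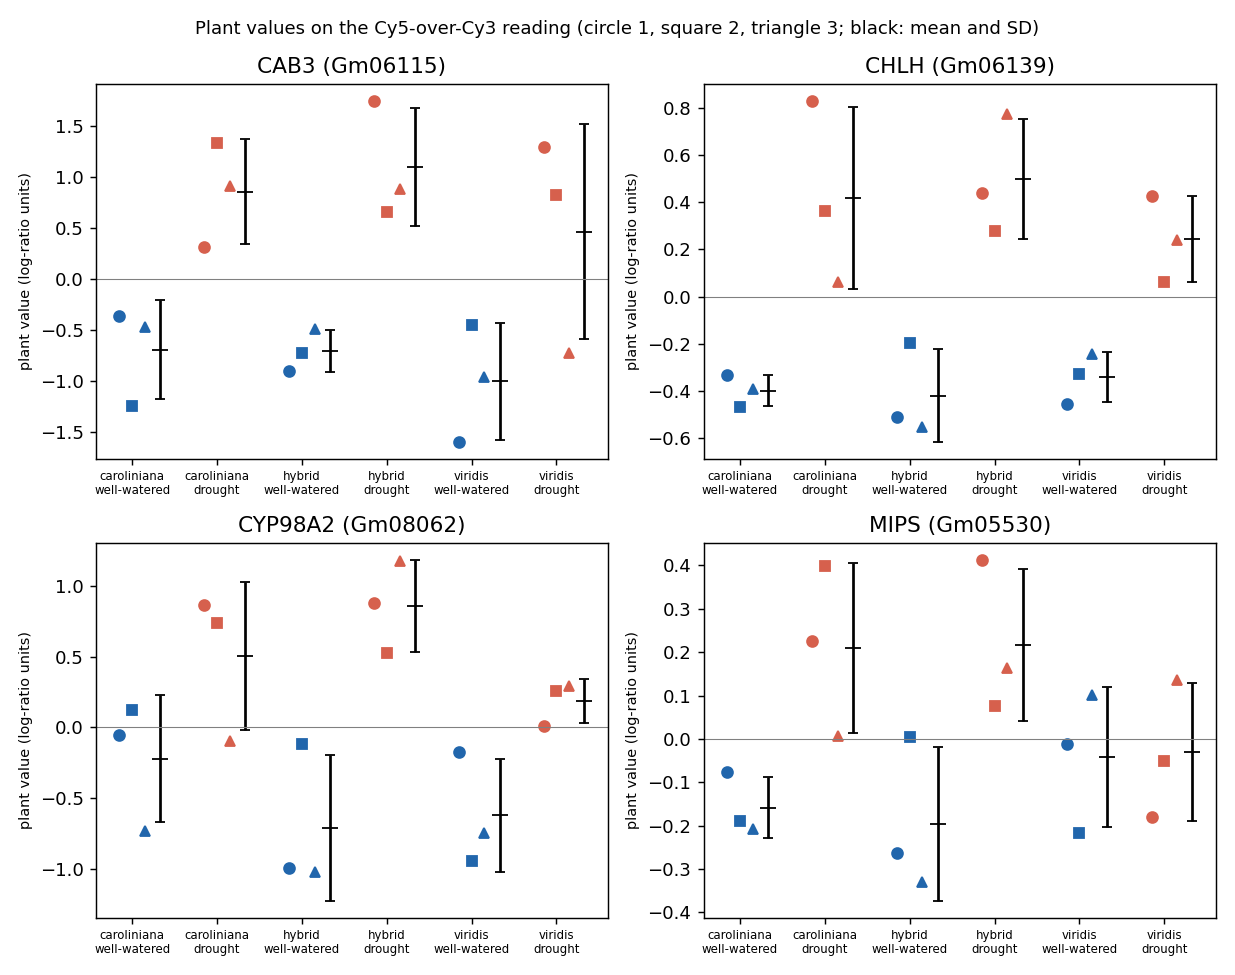
Values of the 18 plants (y axis, log-ratio units on the Cy5-over-Cy3 reading, the opposite reading turns every panel upside down) for 1 probe each of CAB3, CHLH, CYP98A2 and MIPS in the 6 groups (x axis), with circles, squares and triangles for plants 1 to 3 and black bars for mean and SD (n = 3). The mean of CAB3 Gm06115 was -0.70 in well-watered and 0.85 in drought plants of caroliniana, -0.71 and 1.09 in the hybrid, and -1.0 and 0.46 in viridis, where drought plant 3 lay at -0.73. The array marked BAD is 1 of the arrays of that plant. Plant values carry array error shared along the loop, so the points are not independent.

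Per plant, CAB3 Gm06115 had a mean of 1.09 ± 0.577 (SD, n = 3) in drought and -0.71 ± 0.210 in well-watered hybrid plants, 0.85 ± 0.513 and -0.70 ± 0.485 in caroliniana, and 0.46 ± 1.06 and -1.0 ± 0.575 in viridis. CHLH Gm06139 had 0.50 ± 0.255 and -0.42 ± 0.196 in the hybrid, 0.42 ± 0.387 and -0.40 ± 0.0672 in caroliniana, and 0.24 ± 0.183 and -0.34 ± 0.105 in viridis. For CAB3 Gm06115, CAB3 Gm05985, CHLH and CYP98A2, 9 of 9 drought plants lay on the positive side of the well-watered mean of their own morphotype. For MIPS this held for 6 of 9 with Gm03671 and 7 of 9 with Gm05530. In hybrid well-watered plant 2, CAB3 Gm06115 (-0.73) and CHLH (-0.20) lay on the side of the well-watered plants. All these plant values carry array error shared along the loop, so the SDs and counts are not those of independent measurements.

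The called probes were unevenly spread along the clone numbers. Of the 118 positive calls, 68 lay among the 250 tested probes numbered 5602 to 6120, where they made up 27.2%, against 0.655% of the 7630 tested probes elsewhere. The called LOC547820 probe, CHLH Gm06047 and the CAB3 probes Gm05769, Gm05985 and Gm06115 lay in this stretch, whereas the called CHLH probe Gm06139, CAB3 Gm01099, CYP98A2 and MIPS lay outside. The edges are only those of the 250 consecutive tested probes with the most positive calls. CHLH Gm06139 lies just past the upper edge and MIPS Gm05530 shortly before the lower one. Neither is thus clearly separate from the crowded stretch. A single negative call lay inside.

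**Figure D2:**
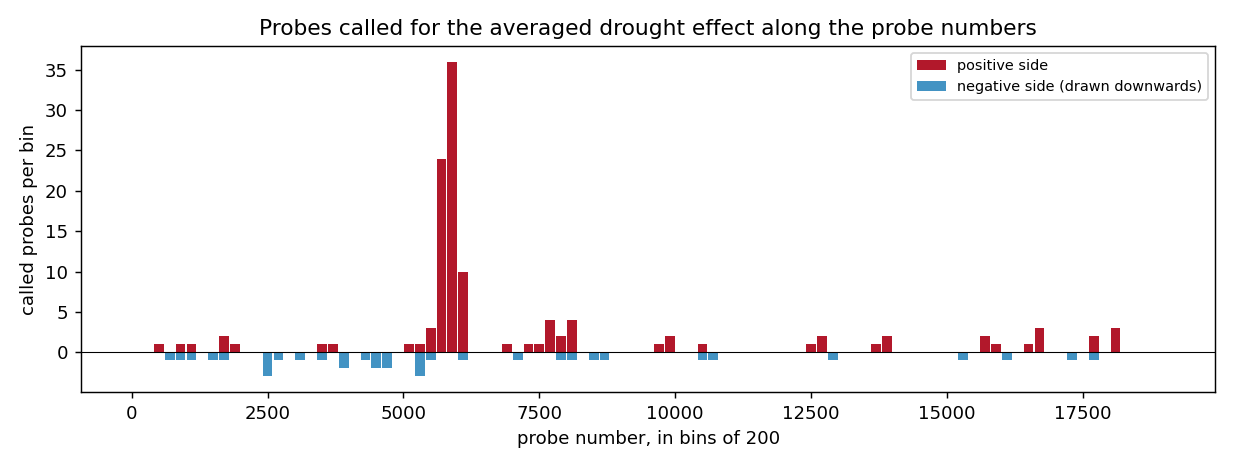
Probes called for the averaged drought effect (y axis, called probes per bin) along the probe numbers (x axis, bins of 200), with the positive side upwards in red and the negative side downwards in blue on the Cy5-over-Cy3 reading. Of 118 positive calls, 68 lay between numbers 5602 and 6120.

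Gene groups could be examined only in part. Of the 16 lists drawn up for a leaf under drought, 13 matched no symbol on the array, among them the lists for abscisic acid and dehydration response, light harvesting, aquaporins, leaf senescence, and the markers of trichomes, guard cells and vascular cells. The antioxidant list matched APX1 and CAT1, which remove hydrogen peroxide as ascorbate peroxidase and catalase. With all plants neither passed the test, with 0.19, 0.28 and -0.03 for the APX1 probes Gm05083, Gm02338 and Gm05712 (adjusted p = 0.226, 0.603 and 0.953), and 0.37 for CAT1 (adjusted p = 0.375). Single plants moved these values. Gm02338 was 0.0479 without caroliniana drought plant 2, 0.0566 without its well-watered plant 1, and 0.421 and 0.425 without its drought plant 1 and well-watered plant 2. Gm05083 was 0.118 without hybrid well-watered plant 1 and 0.120 without hybrid drought plant 2, and CAT1 0.244 without caroliniana drought plant 2, while CAT1 passed without hybrid well-watered plant 2 (0.521, adjusted p = 0.0168). Gm05712 changed sign without 4 of the 18 plants (-0.101 to 0.0434) and was 0.0012 when arrays were scaled alike. F3H, the flavanone 3-hydroxylase of the flavonoid list, had -0.07, -0.04 and -0.05, and the reference gene GAPC1, cytosolic glyceraldehyde-3-phosphate dehydrogenase, had 0.08 and, for Gm01799, 0.06, which turned to -0.0389 with weighted, independent arrays. With 1 plant left out F3H Gm18488 (-0.111 to 0.0154) and GAPC1 Gm01799 (-0.0618 to 0.257) also changed sign, and F3H Gm18512 ran from -0.0888 to -0.00281, F3H Gm15646 from -0.102 to -0.0338 and GAPC1 Gm03248 from 0.0199 to 0.189. With all plants none of these passed, and no list reached the 3 members needed for a set test.

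A further 9 lists were formed from the soybean symbols after the symbols and some values had been seen, so they are not independent evidence. Chlorophyll synthesis and photosystem genes changed to the positive side as a set (camera, adjusted p = 2.12e-04, and adjusted p = 2.58e-04 with an estimated correlation). A gene's value on an array was the mean of those of its probes that had one there, so it can differ from the mean of the probe effects. Of the 5 genes, CAB3 (2.04 ± 0.242) and CHLH (0.75 ± 0.120) passed over all genes. Adjusted over the list alone 4 passed, with PSAD, a subunit of photosystem I, at 0.13 ± 0.050 on the side of CAB3, and HEMB, the aminolevulinate dehydratase, at -0.22 ± 0.0834 on the other, while GSA1, the glutamate-1-semialdehyde aminotransferase, had -0.03 ± 0.0605. Antioxidant enzymes did not pass as a set (10 genes, adjusted p = 0.0797, and adjusted p = 0.436 with an estimated correlation), and CAT5, a further catalase, had the largest estimate, 0.70 ± 0.226. Without hybrid well-watered plant 2 both sets passed with the preset correlation (adjusted p = 0.0159 for each), and neither with an estimated correlation (adjusted p = 0.0623 for chlorophyll and photosystem genes and 0.0800 for antioxidant enzymes).

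In the phenylpropanoid and isoflavonoid list of 14 genes, CYP98A2 (0.33 ± 0.0967 over its probes) and IF7GT, an isoflavone 7-O-glucosyltransferase (0.28 ± 0.0819), passed adjusted over the list alone and none over all genes (set test, adjusted p = 0.349). Among 7 lipoxygenase genes VLXB alone passed adjusted over the list alone (set test, adjusted p = 0.557). None passed in either way among 8 seed maturation proteins (adjusted p = 0.791), 30 transcription factors (0.349), 4 proteins of the 14-3-3 family (0.884), 3 genes of cysteine synthesis (0.884) and 3 ribosomal proteins (0.791). The median and the mean of the list differed in sign for the phenylpropanoid list (-0.0023 and 0.04), the seed maturation list (-0.04 and 0.02) and the cysteine list (0.00035 and -0.03). With all plants the set call of chlorophyll and photosystem genes held with an estimated correlation.

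In caroliniana, drought changed 3 CAB3 probes to the positive side, by 2.70 ± 0.529 for Gm01099 (adjusted p = 0.0369), 1.64 ± 0.238 for Gm06115 (adjusted p = 0.00229) and 1.47 ± 0.234 for Gm05985 (adjusted p = 0.00431), while Gm05769 had 1.49 ± 0.502 and did not pass (adjusted p = 0.591). CHLH changed by 0.81 ± 0.141 (adjusted p = 0.00981) and MIPS Gm05530 by 0.35 ± 0.0764 (adjusted p = 0.0471). CYP98A2 had 0.61 ± 0.204 (adjusted p = 0.526). No named probe was called on the negative side. The chlorophyll and photosystem list did not pass as a set (adjusted p = 0.0852, and adjusted p = 0.0922 with an estimated correlation), but did with gene means of complete probes (adjusted p = 0.00199), so this result depends on how missing values enter. In all 63 probes passed, 55 on the positive side (87.3%) and 8 on the negative side, and the positive share was 69.6% with weighted, independent arrays.

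The caroliniana count of 63 was lower without any 1 plant of this morphotype and without several plants of the others. Within this morphotype it was 4 without drought plant 2, 14 without well-watered plant 2, 16 without well-watered plant 1, 23 without drought plant 1, 26 without well-watered plant 3 and 36 without drought plant 3. Through the loop it was also 30 without viridis well-watered plant 1, 33 without viridis well-watered plant 2, 31 without viridis drought plant 2, 40 without viridis drought plant 1, 40 without hybrid drought plant 2 and 106 without hybrid well-watered plant 2. The call of CAB3 Gm06115 ended without caroliniana well-watered plant 2 (1.69, adjusted p = 0.0503) or drought plant 2 (1.56, adjusted p = 0.0964), and that of Gm05985 without well-watered plant 1 (1.45) or drought plant 2 (1.38). The call of CHLH ended without well-watered plant 1 (0.87), 2 (0.60) or 3 (0.82) or drought plant 1 (0.55) or 2 (0.85). Those of CAB3 Gm01099 and MIPS ended without 11 and 16 of the 18 plants, with effects of 2.11 to 3.42 and 0.30 to 0.39. The count was 38 without a dye term, 135 with weighted, independent arrays, 101 with the first component of the residuals as a covariate and 109 without both plants in doubt, hybrid well-watered plant 2 and viridis drought plant 3.

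In the hybrid, drought changed all 4 CAB3 probes to the positive side, by 5.02 ± 0.768 for Gm01099 (adjusted p = 0.00247), 3.43 ± 0.726 for Gm05769 (adjusted p = 0.0214), 2.33 ± 0.237 for Gm05985 (adjusted p = 2.19e-05) and 2.29 ± 0.241 for Gm06115 (adjusted p = 2.74e-05). CYP98A2 changed by 1.34 ± 0.206 (adjusted p = 0.00113). On the opposite side LOC547870 changed by -0.55 ± 0.107 (adjusted p = 0.0077) and LOC547729 by -0.52 ± 0.125 (adjusted p = 0.0413). Chosen after their values were seen, both CHLH probes (1.13 ± 0.260 and 0.87 ± 0.143), the 3 MIPS probes (0.92 ± 0.185, 0.54 ± 0.103 and 0.40 ± 0.0773), APX1 Gm05083 (0.47 ± 0.0927) and VLXB, a vegetative lipoxygenase (0.46 ± 0.110), changed on the side of CAB3, with adjusted p from 0.00220 for CHLH Gm06139 to 0.0396 for VLXB.

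As sets in the hybrid, chlorophyll and photosystem genes changed to the positive side (adjusted p = 2.54e-04, and adjusted p = 3.08e-04 with an estimated correlation), a call that ended without hybrid well-watered plant 2 (adjusted p = 0.0565, and adjusted p = 0.0938 with an estimated correlation). The mean effect of the list did not shrink (0.76, against 0.72 with all plants), but the t values of the other genes, against which the set is tested, spread more (SD 2.42, against 1.62). Antioxidant enzymes passed with the preset correlation only (adjusted p = 0.0383, against adjusted p = 0.319 with an estimated correlation). In the antioxidant list 3 of 10 genes passed adjusted over the list alone. By limma 163 probes passed, 138 on the positive side (84.7%) and 25 on the negative side, and 18 of these probes, for 12 genes, had a name. The count was 1149 without hybrid well-watered plant 2, 65 without hybrid well-watered plant 1, 105 without hybrid well-watered plant 3 and 70 without hybrid drought plant 2. It was 254 when the arrays were scaled alike, 503 with weighted, independent arrays, 392 with the first component of the residuals as a covariate and 1130 without both plants in doubt. The positive share was 54.3% with weighted, independent arrays, 66.6% with that covariate and 42.5% without those plants. The call of LOC547870 ended without hybrid well-watered plant 1 (-0.56, adjusted p = 0.0704), and those of CAB3 Gm05769 and LOC547729 without 8 and 16 of the 18 plants, with effects of 2.39 to 4.24 and -0.62 to -0.45.

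In viridis, drought changed the CAB3 probes Gm06115 by 1.71 ± 0.239 (adjusted p = 0.00152) and Gm05985 by 1.59 ± 0.235 (adjusted p = 0.00197), and CHLH by 0.65 ± 0.142 (adjusted p = 0.0445), to the positive side. CAB3 Gm01099 had 2.97 ± 0.645 (adjusted p = 0.0620), Gm05769 2.24 ± 0.518 (adjusted p = 0.0783) and CYP98A2 0.85 ± 0.204 (adjusted p = 0.0828), which did not pass, and the MIPS probes had 0.08 each. No named probe was called on the negative side. Chlorophyll and photosystem genes changed as a set (adjusted p = 0.00118, and adjusted p = 0.00138 with an estimated correlation), and 1 of the 7 lipoxygenase genes passed over all genes once its probes were averaged. By limma 56 probes passed, 53 on the positive side (94.6%) and 3 on the negative side, with a positive share of 60.9% with weighted, independent arrays and 80.7% without both plants in doubt. An unadjusted p under 0.05 for drought was reached by 382 probes in viridis, 313 in caroliniana and 1081 in the hybrid. Chance gives 394, so neither parent showed an excess over all probes.

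The viridis count was 14 without well-watered plant 1, 14 without well-watered plant 2, 14 without drought plant 2 and 16 without drought plant 1 of this morphotype, and 86 without hybrid well-watered plant 2. It was 189 with weighted, independent arrays, 97 with the first component of the residuals as a covariate and 93 without both plants in doubt. CAB3 Gm06115 missed the threshold without viridis well-watered plant 1 (1.36) or drought plant 2 (1.37), and Gm05985 without well-watered plant 1 (1.4) or 2 (1.57) or drought plant 1 (1.41) or 2 (1.39). CHLH missed it without 14 of the 18 plants, with effects of 0.55 to 0.74. In viridis drought plant 3, CAB3 Gm06115 lay at -0.73, near the well-watered plants. The median position of this plant was 0.510 (95% interval 0.416 to 0.621) on 48 probes called in viridis without it, midway between the groups. It was 0.659 (0.545 to 0.766) on probes called for the averaged effect without it. Of the 2 arrays of this plant 1 is the array marked BAD, and these values rest in part on it. The intervals come from resampling probes, which are not independent, and leave out the spread between plants.

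**Figure D3:**
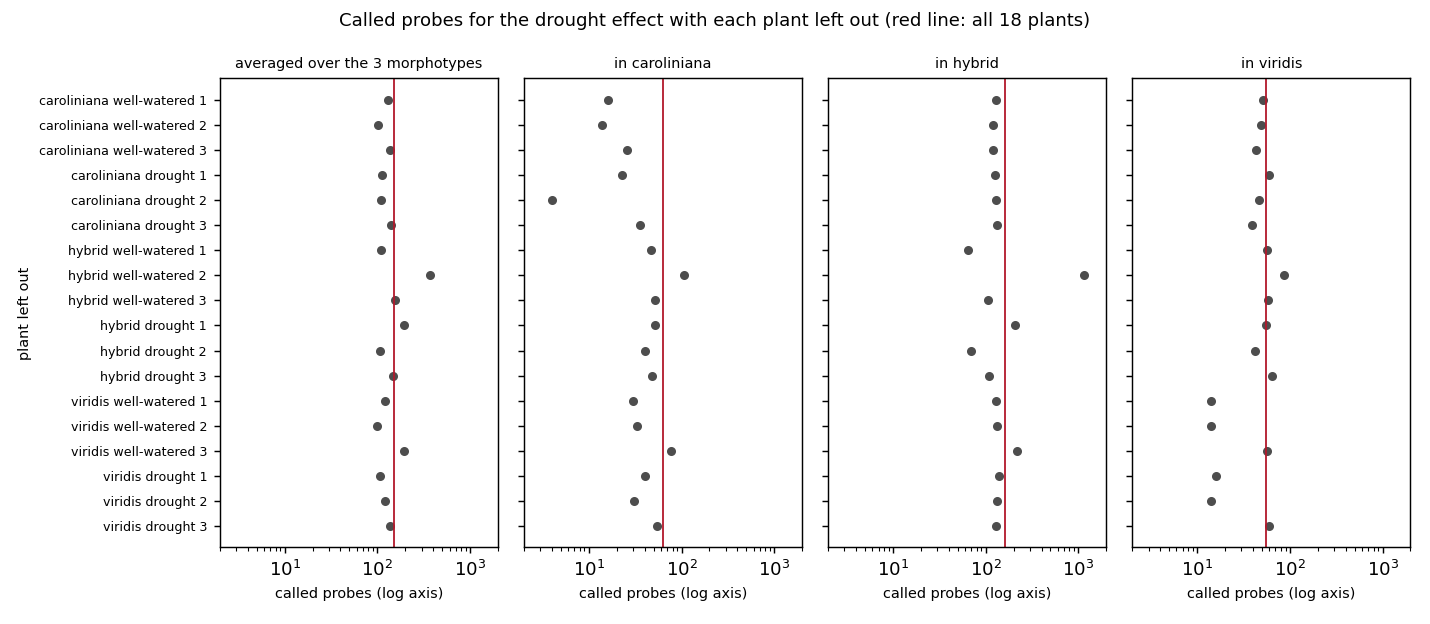
Number of probes called for the drought effect, averaged and in each morphotype (x axes, log scale), with each of the 18 plants left out in turn (y axis), the red line marking the count with all plants. Without hybrid well-watered plant 2 the counts were 373 averaged, 106 in caroliniana, 1149 in the hybrid and 86 in viridis.

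The drought effects of the morphotypes were compared across probes. CAB3 and CHLH were called in every morphotype, and 46 probes were called in all 3, all of them on the positive side, among 169 called in any. Among the called probes of the averaged effect, the median positive effect was 0.79 in caroliniana, 1.22 in the hybrid and 0.77 in viridis, and the median negative effect was -0.43, -0.45 and -0.42. Caroliniana and the hybrid shared 55 positive calls (0.963 expected if calls were independent) and 4 negative calls (0.0254 expected), caroliniana and viridis 46 (0.370) and 2, and the hybrid and viridis 52 (0.928) and 0. Across genes, which are not independent replicates, Pearson's r of the effects was 0.781 for caroliniana and the hybrid, 0.823 for caroliniana and viridis and 0.798 for the hybrid and viridis, with Spearman's rho of 0.350, 0.473 and 0.378. The loop shares arrays between the estimates and gives r of 0.229, 0.226 and 0.239 with no effects at all, and no p was computed.

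**Figure D4:**
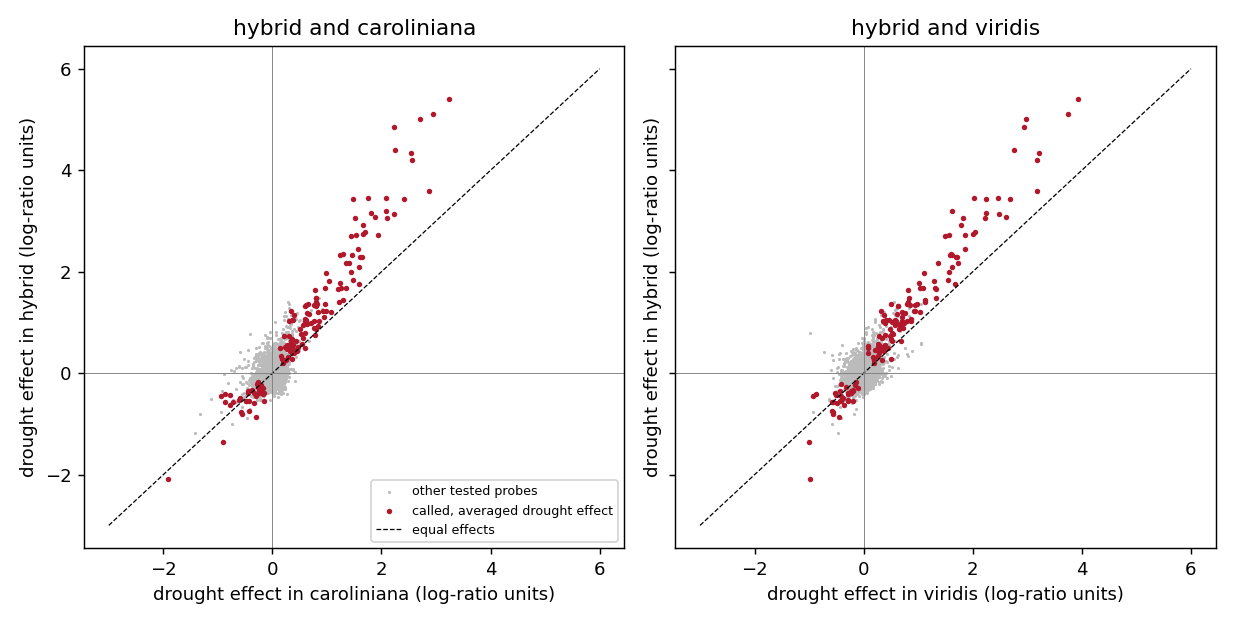
Drought effect in the hybrid (y axes) against that in caroliniana and in viridis (x axes), in log-ratio units on the Cy5-over-Cy3 reading, for the 7880 tested probes, with the 153 called for the averaged effect in red and a dashed line of equal effects. All 153 lie on the same side of 0 in the 3 morphotypes, which their choice by the averaged effect favours.

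Whether drought acted differently in the morphotypes was tested as an interaction, and no probe passed (limma, smallest adjusted p = 0.698, with 185 probes at an unadjusted p under 0.05 where chance gives 394). The named probes with the smallest p belonged to PRX2B, APX1 (Gm05083), MET2 (Gm03898), VLXC, a vegetative lipoxygenase, and MIPS (Gm00068), none past the threshold (adjusted p = 0.998 for each). The larger estimates of CAB3 and CYP98A2 in the hybrid are therefore not shown to differ from those in the parents. Without hybrid well-watered plant 2, however, 124 probes passed, among them that of APX1 (adjusted p = 0.0245), without both that plant and viridis drought plant 3 117, and with weighted, independent arrays 60, against 0 with independent arrays alone. The weights were lowest on the arrays of hybrid well-watered plant 2. Random morphotype labels over all plants called up to 377 probes for this test, so such counts do not by themselves show a difference.

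Caroliniana and viridis were compared over both treatments. The lowest p among named probes belonged to VLXC (0.56 ± 0.143, caroliniana minus viridis), LOC732582 (0.75 ± 0.229), APX1 (0.22 ± 0.0683), SAT1, a serine acetyltransferase of cysteine synthesis (0.17 ± 0.0557), and DAO (-0.18 ± 0.0587), and none passed (adjusted p = 0.855 for each). By limma 0 probes passed and 296 had an unadjusted p under 0.05, where chance gives 394. The median 95% interval of a probe reached 0.162 log-ratio units to each side of its estimate. No left-out plant changed the count, while 7 probes passed with the first component of the residuals as a covariate.

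The hybrid was compared with each parent over both treatments. Against caroliniana the named probes with the smallest p were those of BZIP112, a bZIP transcription factor (-0.36 ± 0.108), CWINV, a cell wall invertase (0.13 ± 0.0449), LOC548038 (-0.28 ± 0.0940), LOC732565 (0.21 ± 0.0740) and APX1 Gm05712 (0.31 ± 0.118), none of which passed (adjusted p = 1.0 for each). Against viridis they were those of LOC732582 (0.47 ± 0.108), APX1 Gm05083 (0.30 ± 0.0698), CAB3 Gm05985 (0.70 ± 0.178), VLXB (0.30 ± 0.0827) and VLXC (0.53 ± 0.146), none of which passed either (adjusted p = 0.473 for each). Single plants moved some of these estimates by over 1.5 times. Without viridis drought plant 3, CAB3 Gm05985 was 0.361 and VLXB 0.186 against viridis. Against caroliniana, LOC548038 was -0.152 without caroliniana well-watered plant 3 and APX1 Gm05712 0.185 without viridis well-watered plant 3. By limma 0 probes passed in both comparisons, and 0 probes lay outside both parents. An unadjusted p under 0.05 was reached by 221 against caroliniana and 767 against viridis, where chance gives 394. The 0 calls against viridis therefore do not show equal expression. Without hybrid well-watered plant 2, 3 probes passed against viridis, and 23 did so with the first component of the residuals as a covariate. The median 95% interval reached 0.168 and 0.165 to each side.

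Whether the hybrid departed from the mean of its parents was tested over both treatments and within each. Over both, CAB3 Gm05985 (0.58 ± 0.155), CWINV (0.14 ± 0.0391), LOC732582 (0.31 ± 0.0938), BZIP112 (-0.31 ± 0.0920) and LOC732565 (0.21 ± 0.0632) had the smallest p among named probes and did not pass (adjusted p = 0.760 for each). Among drought plants APX1 Gm05083 (0.40 ± 0.0787), CAB3 Gm05985 (0.98 ± 0.201), CAB3 Gm01099 (2.04 ± 0.451), LOC547870 (-0.39 ± 0.0905) and VLXB (0.38 ± 0.0933) came closest and did not pass (adjusted p = 0.340 for each). The CAB3 and VLXB estimates fell by over 1.5 times without viridis drought plant 3, a plant in doubt, where CAB3 Gm05985 was 0.334 over both treatments and 0.583 among drought plants, CAB3 Gm01099 0.742 and VLXB 0.239. LOC732582 was 0.207 over both treatments without viridis well-watered plant 3, and APX1 Gm05083 passed among drought plants without hybrid well-watered plant 2 (0.405, adjusted p = 0.0422). Among well-watered plants 1 probe without a gene name, Gm18130, passed at -0.70 ± 0.103 (adjusted p = 0.0459); it was named because it was the only one past the threshold, and after its value was seen.

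Against the mid-parent value 0 probes passed by limma over both treatments (478 at an unadjusted p under 0.05) and 0 among drought plants (779). The well-watered comparison had 258 at an unadjusted p under 0.05, and chance gives 394 in each. Without hybrid well-watered plant 2 the counts were 3 over both treatments, 10 among drought plants and 101 among well-watered plants. The call of Gm18130 passed only without hybrid drought plant 3, viridis drought plant 3, viridis well-watered plant 1 or hybrid well-watered plant 2, and the count was 0 without each of the other 14 plants. It was also 0 when arrays were centred on their medians or scaled alike, without a dye term, with complete probes only, without the array marked BAD, without the array with most missing values, or with the first component of the residuals as a covariate. With weighted, independent arrays 31 probes passed among well-watered and 54 among drought plants, and 25 among drought plants with that covariate. Without both plants in doubt 78 passed among well-watered plants.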

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

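All alternatives were planned except 5, whose choice followed a look at the data. The set tests without hybrid well-watered plant 2 were added, and so were those with gene means of complete probes, which alone changed no averaged set call. The others were the array with most missing values left out, the first residual component as a covariate, and both plants in doubt left out. Counts of called probes are given, and where no cause is stated, the cause was not tested. Array weights were lowest on the 2 arrays of hybrid well-watered plant 2 (0.265 and 0.371). The first residual component loaded most on the same arrays (0.553 and -0.406). The weighted fit, the covariate and the omission of both plants thus all bear on this plant and are not separate evidence. In the simulated data independent arrays gave 37 false calls among 178 for the interaction. Scaling arrays to 1 median absolute deviation gave 252 averaged, 254 in the hybrid and 0 for the well-watered mid-parent comparison, and turned APX1 Gm05712 to 0.0012. Array weights with arrays treated as independent gave 302 averaged, 135 in caroliniana, 503 in the hybrid, 189 in viridis, 60 for the interaction, and 31 and 54 for the mid-parent comparison in well-watered and drought plants, with APX1 Gm05712 at 0.0065 and GAPC1 Gm01799 at -0.0389. The first residual component as a covariate gave 299 averaged, 101 in caroliniana, 392 in the hybrid, 97 in viridis, 7 for caroliniana against viridis, 23 for the hybrid against viridis, and 0 and 25 for the mid-parent comparison in well-watered and drought plants. Leaving out both plants in doubt gave 304 averaged, 109 in caroliniana, 1130 in the hybrid, 93 in viridis, 117 for the interaction, 78 for the well-watered mid-parent comparison and a hybrid and viridis similarity of 0.541. The replicate block gave 38 in caroliniana, 158 averaged, 142 in the hybrid, 47 in viridis and 0 for the interaction; plant numbers do not pair plants by any label, and same-number plants correlated at -0.53 to 0.60 with no common sign. No dye term gave 38 in caroliniana and 0 for the well-watered mid-parent comparison, which was also 0 with median centring, with complete probes only, without the array marked BAD and without the array with most missing values. A threshold of 0.10 gave 239 averaged by its construction.

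With each plant left out in turn the counts ran from 100 to 373 averaged, 4 to 106 in caroliniana, 65 to 1149 in the hybrid, 14 to 86 in viridis, 0 to 124 for the interaction, 0 to 3 for the hybrid against viridis and against the mid-parent value, 0 to 101 and 0 to 10 for the latter in well-watered and drought plants, and 0 to 0 for the other comparisons. Without hybrid well-watered plant 2 the averaged set test of antioxidant enzymes passed with the preset correlation (adjusted p = 0.0159) but not with an estimated one (adjusted p = 0.0800). Similarity ran from 0.574 to 0.850 for caroliniana and the hybrid, 0.732 to 0.825 for caroliniana and viridis and 0.662 to 0.833 for the hybrid and viridis. Among uncalled probes, APX1 Gm05712 ran from -0.101 to 0.0434, F3H Gm18488 from -0.111 to 0.0154 and GAPC1 Gm01799 from -0.0618 to 0.257. Over all alternatives of the named genes, 1820 values kept their direction and side of the threshold, 192 lost the call, 20 gained one and 11 changed sign. The 1820 include many values of probes not called with all plants, which could not lose a call. The share of calls lost is therefore higher than these counts show. Signal over background is unknown, so its effect on small ratios could not be examined.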

Other observations

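The tests chosen only after the result was seen are those of a shift of the whole stretch, of clone carry-over, of a swapped plant and of a wrong label, and the set tests without hybrid well-watered plant 2 or with complete probes, while the Fisher test used a gene list formed after values were seen. Leaving out each plant was planned, but the genes named next were chosen after their values were seen. With hybrid well-watered plant 2 left out, 459 probes were called on the positive side (137 also called with all plants) and 690 on the negative side (22 also called) for drought in the hybrid, whose well-watered group then held only the other two plants. In the antioxidant list, 3 of 10 genes passed over all genes and 3 adjusted over the list alone, all on the side of CAB3, and 4 of 14 probes were called. As a set it passed with the preset correlation (camera, adjusted p = 0.00844) but not with an estimated correlation (adjusted p = 0.0727). The called probes were those of the catalases CAT5 (1.75 ± 0.292 SE, adjusted p = 0.00175 by limma) and CAT1 (1.05 ± 0.180) and of ascorbate peroxidase APX1 with Gm02338 (0.81 ± 0.236) and Gm05083 (0.57 ± 0.0937), while APX1 Gm05712 had 0.06 ± 0.159 and the glutathione transferases, SODB and CCS did not pass. In all, 43 named probes (32 genes) were called on the positive side and 36 (36 genes) on the negative side, of which only a selection is given. Single calls on the positive side, outside any set that passed, included PSAD of photosystem I (0.70 ± 0.104), IF7GT of isoflavone metabolism (0.71 ± 0.131), SAMDC, the S-adenosylmethionine decarboxylase of polyamine synthesis (0.73 ± 0.139 and 0.47 ± 0.139), and the aquaporin PIP2-6 (0.41 ± 0.119). Those on the opposite side included GAI1, a growth-repressing regulator of gibberellin response (-0.61 ± 0.116), the NAC transcription factor NAC2 (-0.40 ± 0.106) and the ribosomal protein gene RPL2 (-0.43 ± 0.0940). With all plants CAT5 had 1.16 (adjusted p = 0.0980), CAT1 0.66 (adjusted p = 0.183) and GAI1 -0.34 (adjusted p = 0.283).

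Without that plant 124 probes passed the test for a drought response that differs between the morphotypes, 8 of them named. Of the 124, 120 were also called in the hybrid. APX1 Gm05083 had 0.57 in the hybrid against 0.07 in caroliniana and 0.02 in viridis (adjusted p = 0.0245). LOX1.1, a lipoxygenase, had 0.39 against -0.45 and -0.61 (adjusted p = 0.0109), and PRO2 had 0.70 against 0.01 and -0.22 (adjusted p = 0.0116). With all plants no probe passed this test by limma, and 185 had an unadjusted p under 0.05. These differences rest on the plant being rightly left out. Splits with random morphotype labels over all plants called up to 377 probes for this test, and none were drawn without the plant. Chance therefore cannot be excluded for the 124.

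That plant lay near the drought plants on 970 complete probes called for drought in the hybrid without it. Its median position there was 0.888 (95% interval 0.856 to 0.922) on a scale from 0 for the other well-watered to 1 for the drought plants. On 87.1% of probes it lay nearer the drought plants. This interval and those below come from resampling probes, which are not independent. They therefore leave out the spread between plants. On the directions used here, both arrays of this plant placed it near the drought plants (1.1, and 0.743 with an interval of 0.706 to 0.785). A fault of 1 array stays open all the same. The value of 0.743 comes from the array with viridis well-watered plant 3, whose turned sign lowered the residual sum of squares (0.951). The position with that array turned was not computed. A drought plant carrying a well-watered label may be the source, since on probes called for the averaged effect without it the position was 0.725 (0.696 to 0.782), against 0.725 for hybrid drought plant 2 but 1.1 and 1.12 for the other hybrid drought plants, and its CAB3 and CHLH values lay with the well-watered plants. The position of hybrid drought plant 2 rests in part on the array marked BAD, so this match is weak. A swap stays open without a clear partner. Exchanging the label of hybrid well-watered plant 2 with 7 of 9 drought plants lowered the residual variance (ratio as geometric mean over probes), most with caroliniana drought plant 1 (0.832). Exchanges of other plants lowered it too, as 13 of all 81 exchanges did, the lowest being hybrid well-watered plant 3 with viridis drought plant 3 (0.950). The position of caroliniana drought plant 1 was 0.546 (0.440 to 0.622) on probes called without both it and hybrid well-watered plant 2. It was 0.814 (0.722 to 0.926) on those called without caroliniana drought plant 1 alone, whose CHLH value of 0.83 was the highest of the 18 plants. Viridis drought plant 3 lay at 0.818 (interval from 0.688 upwards) on probes called without it and hybrid well-watered plant 2. No biological explanation, such as the water status of hybrid well-watered plant 2, was tested.

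The positive calls of the averaged effect crowded among probe numbers 5602 to 6120, 68 of 250, whereas the highest count for 250 consecutive probes in 10000 random orders was 16 (permutation p = 1e-04, the smallest they can give). A shift of every probe of the stretch by print or plate position is argued against, since the lower quartile of its effects was -0.0354 (-0.0547 to -0.0045), while outside it was -0.0740, so that a shift by 0.25 of the calls' median would put it at 0.158 (a smaller shift is not excluded). Grouping of photosynthesis clones in the numbering stays open: 5 of 31 named probes inside and 5 of 436 outside belong to the chlorophyll and photosystem list (two-sided Fisher exact p = 1.86e-04), but 3 of the 5 are CAB3 calls that define the stretch, so this test decides nothing. A clone carried into neighbouring wells also stays open, as the residuals of the other positive calls inside correlated with those of the CAB3 probes there with a median of 0.379 (0.303 to 0.486), though the positive calls outside gave 0.327 as well and other probes -0.03. CAB3 Gm01099, which lies outside, changed on the same side, and whether unnamed calls of the stretch are further light-harvesting genes was not tested.

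On 128 called complete probes the mean size of the drought effect was 1.23 in the hybrid, 0.821 in caroliniana and 0.853 in viridis, a difference of the hybrid from the parental mean of 0.390 ± 0.144 (SE). Of the 128 probes, 2 of CAB3 and 60 others are positive calls numbered 5602 to 6120, where clone carry-over stays open. The difference was not computed without these probes. Wider ratios on arrays of hybrid plants are argued against as the cause, since the difference was 0.484 ± 0.149 after scaling the arrays alike. Chance allocation of plants to morphotypes cannot be excluded (two-sided permutation p = 0.0735, 100000 permutations). A single plant stays open by the bound set beforehand, as the difference came within 2 standard errors of 0 without hybrid well-watered plant 1 (0.255 ± 0.140) or 3 (0.300 ± 0.169), but these drops are smaller than their standard errors, it was positive without each of the 18 plants, and it was 0.60 ± 0.0792 without hybrid well-watered plant 2. A stronger response of the hybrid stays among the open explanations.

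Other splits of the plants into groups of the same sizes were counted. For the averaged drought effect chance is an unlikely source of the count as a whole. The real split called 153 probes, the highest of the others 2, and 1 of 100 splits, the real one, called as many. That is the smallest share that 100 splits can give, and it does not test single probes. Within a morphotype the 10 splits are too few for a share under 0.05, with 63 real calls and 0 at most otherwise in caroliniana, 163 and 4 in the hybrid, and 56 and 0 in viridis. Chance cannot be excluded for the single call of the well-watered mid-parent comparison, where 6 of 100 splits called as many and the highest other 8. For the comparisons with 0 calls every one of the 100 splits calls as many by construction, and the highest other count was 377 for the interaction, 88 for caroliniana against viridis, 145 and 80 for the hybrid against caroliniana and viridis, 90 for the hybrid against the mid-parent value, 34 for the same among drought plants and 1 for the hybrid outside both parents. Splits that call many more probes than the real one point to a structure of the samples, whose source was not tested.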
